A study of Homo sapiens with 4 samples.

How the data were processed

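Genomic DNA of ACHN cells carrying dCas9 and a guide library was sequenced, per the labels' protocols after selection of transduced cells with puromycin and amplification of the guides by PCR in a pair of rounds. The submitters' processing notes name bcl2fastq, MAGeCK (a tool that counts guides and tests screens) and the build GRCh38, without versions. The deposited signal values are RPM (reads scaled to an equal total per library) plus 1: each column sums to 1012468, which holds an added 1 for each of the 12468 guides, and a guide without a read is listed at 1. The file has 1 column per library, and 0 columns were left unmapped. After subtracting 1, all values (100.0%, tolerance 0.01 reads) were whole multiples of the worth of 1 read, which gave the library totals: 15098809 and 9927424 reads for D0 and D12 of clone 1, and 6536374 and 4839104 for clone 6. The floor of 3 reads lay at 0.199, 0.302, 0.459 and 0.620 RPM in these libraries. PCR reads without molecular identifiers are not independent molecules, so read counts cover counting error only. Guides listed at 0 reads numbered 694, 712, 705 and 742.

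No read was found in any library for 693 guides, 670 of them in 40 runs of at least 10 consecutive guides, and 34 targets had no guide with a read. These guides entered no test. Target names were matched to RefSeq genes (GRCh38.p14): 144 by symbol, 30 by an older symbol and 626 not at all. Coordinates are printed for matched genes only.

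The main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend) on log2(RPM + 1), which is the log2 of the deposited value, over guides with a mean of at least 30 RPM, with time point as the only term. A fold change on this scale understates the change of low guides. Benjamini-Hochberg adjustment was made over the 11472 guides tested. MAGeCK was not used here. Genes were tested by alpha-RRA, the rank aggregation that MAGeCK uses, written in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3; figures with matplotlib 3.10.9). Guides were ranked by the moderated statistic, the top 25% counted, and each one-sided p came from 100000 random guide sets of the same size, so that 1e-05 was the smallest p it could give. Adjustment was over the 760 genes with at least 3 guides, with a threshold of 0.05. Clone differences were ranked by the difference of log2 fold changes. List shifts used 100000 permutations of gene labels, two-sided. Bootstrap intervals used 2000 draws of genes.

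The clone number pairs D0 with D12, since both come from the same clone: deviations from the time point means of same-clone libraries correlated at 0.807 over 11472 guides. The model without the clone as a block was the main one, fixed before the data were examined, and the blocked model was an alternative. The 2 clones are the replicates, so p-values per guide measure the spread between these libraries, while p-values per gene set the ranks of its guides against random guide sets. Named genes were fixed by a rule before the data were examined: CRNDE, the called genes with the same sign in both clones with the lowest (up to 15) and highest (up to 10) medians, up to 4 called and 2 uncalled members per list, up to 4 genes per direction that differ between clones, and the protein-coding targets. RP11-386G11.10 and RP11-299G20.2, called with medians of opposite sign in the clones, and genes first named under an alternative or in a list of neighbours were named after their values were seen.

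Alternatives included no filter, a filter at 100, pseudocount 10, scaling by median ratios or control guides, the clone as a block, leaving out each clone or library, the top 10% of guides, a null from control guides and a permutation of the mean. Added after seeing the data were voom on recovered reads, ranks by log2 fold change, no filter together with the clone block, blocks of 10 consecutive guides and lists among lncRNA targets alone. In a simulated D12 against D0 comparison of 761 genes, where 60% of a gene's guides changed, the test recovered 50.0%, 95.0% and 100.0% of 20 genes each changed by −0.25, −0.5 and −1.0 on the log2 scale, 100.0% of 20 genes raised by 0.5, and called 0 of 681 unchanged genes. The changed genes were picked among those with every guide above the filter, and both clones had the same change. Loss of guides to the filter and loss before D0 in 1 clone were thus not simulated. The rates do not carry over to genes such as the protein-coding targets, where both occur. The simulated noise had the spread of the negative control guides, while targeting guides spread more widely. The SD of the log2 fold change, mean of both clones, was 0.15 for control and 0.24 for targeting guides. The recovery and the 0 false calls may thus be too favourable.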

Results

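The screen was run in ACHN, an established human renal cell carcinoma line, carrying dCas9, a Cas9 that binds DNA without cutting and, in CRISPR interference, lowers transcription of the gene its guide RNA targets. Guides were read out from genomic DNA of 2 independent clones, clone 1 and clone 6, at D0 (the control samples) and after 12 days of growth (D12), which gave 4 libraries and 2 per time point. A guide whose target the cells need for growth loses reads between D0 and D12. The library listed 12468 guides, of which 12018 targeted 800 genes and 450 were negative controls. Of the targets, 12 were protein-coding genes of the ribosome and DNA replication with 10 guides each. The others are called long non-coding RNA (lncRNA) targets below, although a few names are of other classes, such as the small nuclear RNA RNU12, the microRNA MIR3615 and ZNF888, listed as protein coding. The series title names the lncRNA CRNDE, ribosome biogenesis and proliferation as the subject of the study. Library totals, recovered from the deposited values, were 15098809 reads for D0 and 9927424 for D12 of clone 1, and 6536374 for D0 and 4839104 for D12 of clone 6. The median detected guide had 1229, 810, 532 and 396 reads in these libraries, in the same order, and the Gini index of the guide values rose from 0.248 and 0.267 at D0 to 0.260 and 0.288 at D12 in clones 1 and 6. Values per gene below are the median log2 fold change over its guides, D12 over D0, given as the mean ± SD of the 2 clones.

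Guides against protein-coding genes of the ribosome and of DNA replication lost reads over the 12 days. With every guide that had a read included, all 12 of these genes were depleted: 9 ribosomal protein genes (among them RPL6, RPL8, RPS15A, RPS19 and RPS21), PCNA, the sliding clamp of DNA polymerase, and RPA1 and RPA3, subunits of the single-strand DNA binding protein RPA. RPS15A had −2.17 ± 0.68 and RPS19 −1.96 ± 0.60, and RPA3 showed the smallest loss of the 12 at −0.63 ± 0.37. The alpha-RRA adjusted p lay between 0.00051 and 0.00604. With the planned filter (mean of at least 30 RPM), which removed 79 of the 120 guides of these genes, 7 of the 12 genes had at least 3 guides left and 4 of the 7 were depleted: RPS19 at −1.27 ± 0.30 (adjusted p = 0.00253), RPS15A at −1.53 ± 0.49 (0.0145), RPS21 at −0.67 ± 0.56 (0.0106) and RPA3 at −0.55 ± 0.65 (0.0205). RPA1 at −0.92 ± 0.15 (0.0583), RPL8 at −0.09 ± 0.22 (1.0) and PCNA at 0.02 ± 0.06 (0.72) did not pass under the filter. With the clone as a block, which keeps the pairing, RPA1 passed under the same filter (0.0123). The filter keeps guides by their mean over D0 and D12 and so removes guides that fall. Over all 10 guides RPL8 had −0.89 ± 0.59 and PCNA −1.14 ± 0.53. Of the 7 genes, 5 passed without clone 1 and 4 without clone 6, and none passed without only the D12 library of clone 6 or only the D0 library of clone 1, where the remaining libraries are no longer paired by clone. With voom, RPS15A (adjusted p = 0.644), RPA3 (0.183) and RPS21 (0.104) lost their call.

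**Figure D1:**
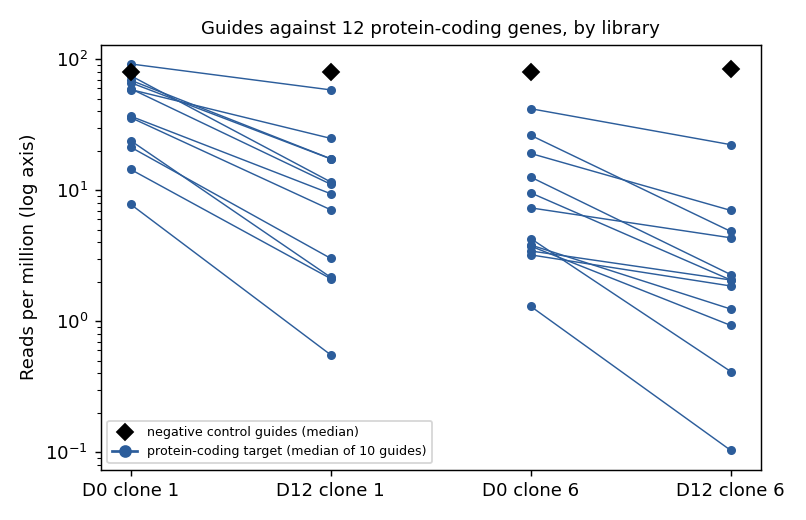
Median RPM (log axis) of the 10 guides of each of 12 protein-coding genes in the 4 libraries, with lines joining D0 and D12 of a clone, and the median of the 450 negative control guides as black diamonds. Over all 120 guides the median was 36.1 at D0 and 4.23 at D12 in clone 1, and 5.28 and 1.65 in clone 6, while the controls stayed between 80.1 and 83.8.

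As a set, these guides had lower levels than the controls at D0, and lower in clone 6 than in clone 1. The median over the 120 guides was 36.1 RPM at D0 in clone 1 and 5.28 in clone 6, against 80.1 and 80.2 for the negative controls. For RPS15A guides the D0 median was 75.0 in clone 1 and 9.56 in clone 6, for RPL6 guides 7.82 and 1.30, and for RPA3 guides 92.3 and 42.0, in clone 1 above the controls. Per guide, the D0 level of clone 6 relative to clone 1 had a median of −2.05 (SD 1.06, 120 guides) on the log2 scale, and 0.01 (SD 0.35, 450 guides) for the controls. The D0 libraries are 1 per clone, so this difference has no replicate check.

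Among lncRNA targets, 13 were depleted under the filter. The largest losses were RP4-705D16.3 at −0.87 ± 0.92 (adjusted p = 0.0038), EPB41L4A-AS1, a host of the small nucleolar RNA SNORA13, at −0.45 ± 0.35 (0.00253), and PXN-AS1, antisense to the paxillin gene PXN, at −0.36 ± 0.17 (0.00304). Over all guides with a read RP4-705D16.3 had −1.28 ± 1.30, PXN-AS1 −0.95 ± 0.05 and EPB41L4A-AS1 the same −0.45. RP11-486O12.2 had −0.29 ± 0.03 (0.00507), LINC00493 −0.24 ± 0.22 (0.0038), FGD5-AS1 −0.13 ± 0.08 (0.0038), RP11-573G6.10 −0.12 ± 0.07 (0.0239), RP11-315I20.1 −0.11 ± 0.12 (0.00304; −0.18 over all guides) and AC093702.1 −0.09 ± 0.06 (0.0367). PCBP1-AS1 (184 guides, 0.00253), SNHG12 (60 guides, 0.0184), RP11-386G11.10 (30 guides, 0.0332) and RP11-299G20.2 (10 guides, 0.0332) also passed, with medians over all guides of −0.01, 0.01, −0.05 and −0.14. The rank test reads the lowest guides of a gene, so a gene with many guides can pass with a median near 0, and the sign of the SNHG12 median turned in several alternatives. With the clone as a block, SNHG12 (adjusted p = 0.114), RP11-573G6.10 (0.072), AC093702.1 (0.67) and RP11-386G11.10 lost their call. Most of the 13 also lost their call without the D0 library of clone 1, which breaks the pairing by clone. With voom, RP4-705D16.3 (0.247) and RP11-315I20.1 (0.173) were among the 5 that lost it.

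Positions below are from GRCh38.p14, the patch release of the build the submitters name. EPB41L4A-AS1 lies on chromosome 5 at 112160526 to 112162501, within the span of EPB41L4A. PXN-AS1 lies on chromosome 12 at 120201291 to 120212828, overlaps PXN and lies 180 bp from RPLP0, a ribosomal protein gene at 120196699 to 120201111. PCBP1-AS1, on chromosome 2 at 69962263 to 70088208, overlaps PCBP1, which encodes an RNA-binding protein. FGD5-AS1, on chromosome 3 at 14942779 to 14948441, overlaps the nuclear receptor gene NR2C2, and SNHG12, on chromosome 1 at 28578538 to 28582983, holds SNORA16A, SNORA44, SNORA61 and SNORD99. LINC00493 is an older name of SMIM26, listed as protein coding, on chromosome 20 at 18567432 to 18569611. The positions of single guides within these genes are not given in the sources used here.

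In all, 17 of 760 genes tested were depleted and 1 was enriched at an adjusted p under 0.05, and 52 and 38 genes had an unadjusted p under 0.05. The enriched gene, AC019117.1, rose by 0.15 ± 0.04 (adjusted p = 0.0456), and over its alternatives the adjusted p ranged from 0.0304 to 0.981. Without the filter 29 genes were depleted (12 protein-coding, 17 lncRNA) and 0 enriched, and 16 of the 17 genes were shared. KB-1043D8.6, at −0.27 ± 0.40 (0.0584) under the filter, was depleted without it at −0.997 ± 0.16 (0.00051). The count fell when single libraries were left out, most without the D0 library of clone 1 and without the D12 library of clone 6. Leaving out 1 library breaks the pairing by clone, so the D0 difference between the clones enters the fold change. These falls thus do not show how far the calls rest on 1 library. Tests within each clone, which keep the pairing, are given below. No single guide passed in the limma fit of 11472 guides, where 53 guides were lower and 1 higher at an unadjusted p under 0.05. These are fewer than chance alone gives at that threshold. The fit has no clone term, so the differences between clones (same-clone deviations correlated at 0.807) count as error. Its 0 thus does not show that no guide changed. The voom fit, which has no clone term either, called 0. The fit with the clone as a block called 284 lower and 8 higher. That blocked fit also called 5 of the 445 negative control guides lower and 1 higher, so part of its calls can arise without a target.

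**Figure D2:**
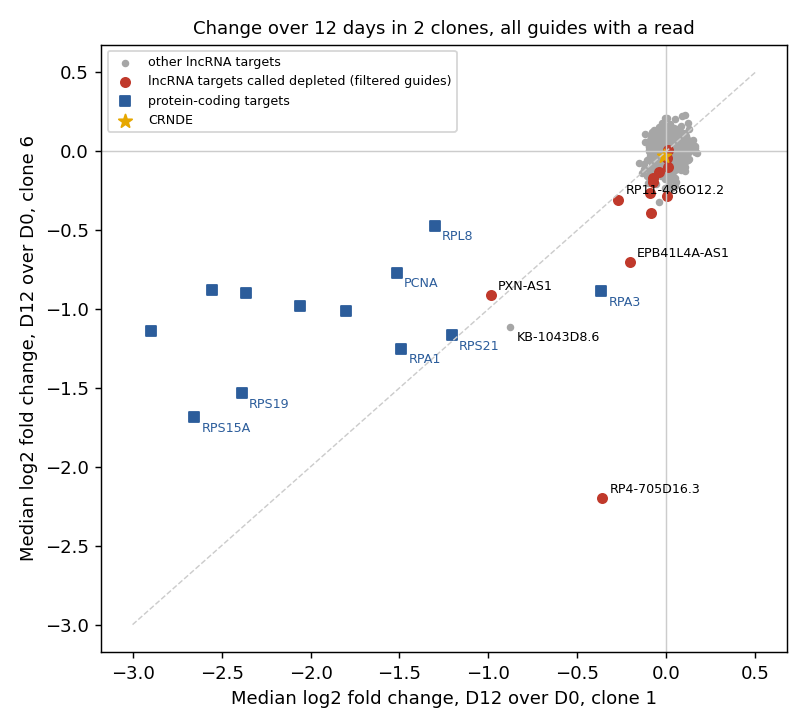
Median log2 fold change of each gene, D12 over D0, in clone 1 (horizontal axis) and clone 6 (vertical axis) over all guides with a read, with the line of equal change dashed. Protein-coding targets are squares, labelled where they were tested under the filter, with RPS15A at −2.65 in clone 1 and −1.69 in clone 6. RP4-705D16.3 lies at −0.36 in clone 1 and −2.20 in clone 6, and CRNDE (star) lies at −0.01 and −0.03.

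CRNDE guides as a set did not pass the test. Its 39 tested guides had a median log2 fold change of −0.01 in clone 1 and −0.03 in clone 6 (mean −0.02 ± 0.01), with a one-sided permutation p of 0.0377 that adjusted to 0.597. The 2 lowest guides, picked after seeing the data, had −0.70 and −0.47 in clone 1 and −1.98 and −1.74 in clone 6. At D0 they lay lower in clone 6 by −2.04 and −1.16 on the log2 scale. No CRNDE guide passed alone, but neither did any of the 11472 guides in that fit, those of protein-coding targets included. Without a clone term, a D0 difference between the clones adds to the error of a guide there, so this does not speak against single guides. CRNDE lies on chromosome 16 at 54918863 to 54928886, 1979 bp from the developmental transcription factor gene IRX5. Its 40 guides were listed as 1 run of consecutive numbers. In a division of all genes into blocks of 10 consecutive guides, chosen after seeing the data, the third CRNDE block had a median of −0.01 in clone 1 and −0.29 in clone 6 (adjusted p = 0.165 over 1135 blocks, 0.191 without the filter and 0.0431 with the clone as a block). The other CRNDE blocks had adjusted p values for depletion of 1.0 in the same test.

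Gene lists fixed before the data were examined divided by class. Of 4 ribosomal protein genes tested under the filter, 3 were depleted, also adjusted over the list alone, with a shift of the mean against other genes of −0.90 (permutation adjusted p = 5e-05), and without the filter 9 of 9 were depleted (shift −1.61). Of 3 core essential genes, RPA3 was depleted and RPA1 and PCNA were not, though RPA1 passed with the clone as a block (alpha-RRA adjusted p = 0.0123). Adjusted over the list alone 2 were depleted, and the shift was −0.49 (permutation adjusted p = 0.0111). Without the filter 3 of 3 were depleted (shift −1.03, 0.00097). Without clone 6 the shifts were −0.63 (1e-04) for ribosomal proteins and −0.29 (0.0291) for core essential genes, and without only its D12 library, which sets D12 of clone 1 against D0 of both clones, −0.05 (0.541) and −0.03 (0.549). Of 8 snoRNA host genes, EPB41L4A-AS1 and SNHG12 were depleted (3 adjusted over the list alone). Their shift of −0.08 did not pass (permutation p = 0.0448, adjusted 0.112). Among lncRNA targets alone it was −0.09 (permutation p = 0.00975, adjusted 0.0552), which did not pass either. Both are shifts of means: the median of the 8 was −0.02, with EPB41L4A-AS1 at −0.45 and SNHG12 at 0.01. Without the D0 library of clone 1, which breaks the pairing by clone, the shift against all other genes was −0.09. ZFAS1, a host of SNORD12, had −0.15 ± 0.07 (0.086) and SNHG15 −0.08 ± 0.04 (0.597).

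Of 8 kidney cancer lncRNAs only SNHG12 was depleted (1 adjusted over the list alone), and HIF1A-AS2, antisense to the hypoxia factor gene HIF1A, had 0.07 and MALAT1 0.05. Under the filter none of 20 cancer-associated lncRNAs was called in either direction or adjusted over the list alone (shift 0.01, adjusted p = 0.813); without it MIR210HG was depleted at −0.12 (0.0372). Of 72 antisense names 4 were depleted (4 adjusted over the list alone), and the shift was −0.01 (0.813). Among uncalled members EZR-AS1 had −0.13 (0.178) and NCAM1-AS1 −0.09 (0.519). EZR-AS1 gained a call with a null from control guides, and without the D0 library of clone 1, which breaks the pairing by clone. LINC names gave 1 of 39 (LINC00493; 1 over the list alone), with LINC00264 at −0.08 and LINC00707 at 0.08, and SNHG names 1 of 4 (SNHG12), with SNHG7 at 0.02. MicroRNA host names gave 0 of 3, and 1 adjusted over the list alone. Clone-based names gave 7 depleted and 1 enriched of 601 (3 and 1 adjusted over the list alone), with RP11-290L1.3 at 0.16 uncalled. Their shift of 0.05 (adjusted p = 5e-05) was against genes that include the protein-coding targets, and among lncRNA targets alone it was 0.01 (0.0552). Divergent names and growth-restraining genes had 0 measured members, and growth-restraining lncRNAs, partners of an essential gene and housekeeping RNAs had 2, 2 and 1, too few to test.

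Negative control guides had a median log2 fold change of 0.02 (SD 0.15, 445 guides), and targeting guides 0.01 (SD 0.24, 11027 guides). The means differed by 0.04 (permutation test, two-sided, 100000 resamples, p = 0.00308), and above a mean of 100 RPM by 0.01 (p = 0.316).

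Depletion was shared between the clones. Tested within each clone, which compares 2 libraries, 12 genes were depleted in clone 1 and 14 in clone 6, and 9 in both, where independent lists would share 0.221 (Fisher's exact test, p = 1.95e-15). The shared genes were RPS15A, RPS19, RPA1, RPA3, EPB41L4A-AS1, PXN-AS1, PCBP1-AS1, RP11-315I20.1 and KB-1043D8.6. Across 760 genes, which are not independent replicates, the medians of the clones correlated with a Pearson r of 0.646 (95% bootstrap interval 0.341 to 0.795) and a Spearman rho of 0.152. The correlation was 0.283 over 753 lncRNA genes and 0.117 above a mean of 100 RPM. Over 739 genes without a call of depletion, in the main test or within a clone, it was 0.119.

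The size of the change differed between the clones for 4 genes. RP4-705D16.3 had −0.22 in clone 1 and −1.53 in clone 6 (median difference per guide 1.43, permutation adjusted p = 0.0076), RPA3 −0.10 and −1.01 (0.69, 0.0101) and RP11-315I20.1 −0.03 and −0.20 (0.24, 0.0076). PXN-AS1 guides ranked lower in clone 1 (adjusted p = 0.0152), with means over 8 guides of −1.11 in clone 1 and −0.53 in clone 6, while its medians ran the other way, −0.24 and −0.49. These tests compare the 4 libraries, since no residual degrees of freedom are left for an interaction. Above a mean of 100 RPM 0 genes differed, but RP4-705D16.3, RPA3 and PXN-AS1 had too few guides to be tested there. That 0 therefore does not speak on these genes. Without the filter 16 genes differed, 14 with guides ranked lower in clone 1 (11 of them protein-coding targets) and 3 in clone 6, with RP11-315I20.1 in both. The protein-coding targets thus turned with the filter: over all 120 guides the median change was −2.02 in clone 1 and −1.07 in clone 6. In clone 6 they began from 5.28 RPM, against 36.1 in clone 1, which on this scale leaves less room to fall.

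**Figure D3:**
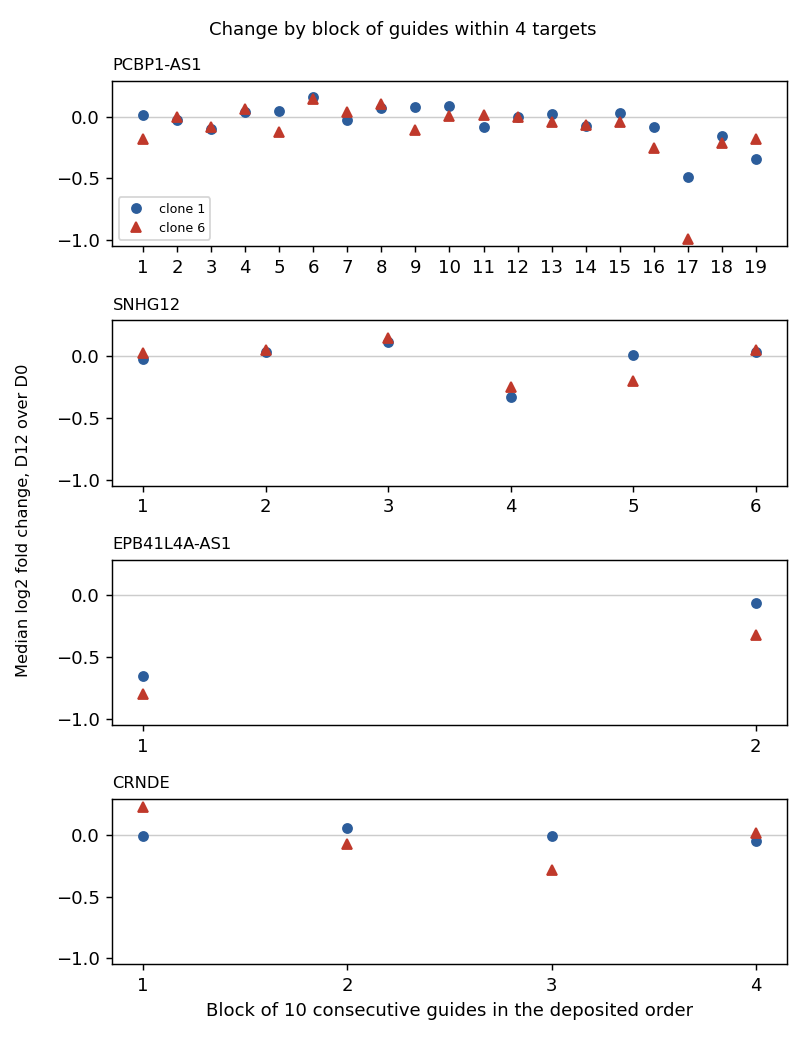
Median log2 fold change, D12 over D0, of each block of 10 consecutive guides in PCBP1-AS1, SNHG12, EPB41L4A-AS1 and CRNDE, with clone 1 as circles and clone 6 as triangles. PCBP1-AS1 block 17 lies at −0.48 in clone 1 and −0.99 in clone 6, and SNHG12 block 4 at −0.33 and −0.25.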

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

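All tests of explanations in this part were chosen after the results were seen. RP4-705D16.3, RP11-315I20.1 and RPA3 guides were more depleted in clone 6, by a median difference of 1.43, 0.24 and 0.69 on the log2 scale (adjusted p = 0.0076, 0.0076 and 0.0101), which a test of the difference itself picked out. Without the filter the differences were 1.29 for RP4-705D16.3, 0.47 for RPA3 and 0.15 for RP11-315I20.1, with adjusted p values up to 0.0331, but RP11-315I20.1 guides then also ranked lower in clone 1 (0.000765), so the part of the filter stays open. The protein-coding targets turned with the filter: under it the median of all 7 tested was lower in clone 6, and without it that of 11 of 12 was lower in clone 1. Without the filter their guides began at D0 from a median of 36.1 RPM in clone 1 and 5.28 in clone 6. With the added 1, the lower start leaves less room to fall, so this turn does not show a stronger effect in clone 1. A stronger effect in clone 6 on these 3 genes that had begun before D0 remains possible. The 44 guides of these genes were also lower at D0 in clone 6 (median −0.26). Random guide sets matched this in a share of 0.0001, the smallest that 10000 sets can give. A lower D0 level cannot tell a stronger effect from the same effect further along in clone 6. All 12 protein-coding targets were also lower at D0 in clone 6. With 1 library per clone and time point, a difference between cultures or libraries cannot be separated from one between the clones themselves.

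PXN-AS1 guides ranked lower in clone 1, with a median difference of −0.24 per guide (adjusted p = 0.0152). Whether a lower D0 level in clone 6 is the whole cause stays open: the D12 levels differed by a mean of −0.39, clone 1 minus clone 6 (permutation p = 0.00196 over 8 guides), but by 0.24 without the 2 guides that differ most. The difference in ranks may rest on these 2 guides, which changed by −3.05 and −3.77 in clone 1 and by −0.73 and −1.62 in clone 6: without them the mean difference was −0.03, a value that random sets trimmed the same way matched in a share of 0.0657. No biological explanation was tested for this gene.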

How the results depend on the processing

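Alternatives added after seeing the data are voom, ranks by log2 fold change, no filter with the clone block, blocks of guides, and lists among lncRNA targets. Of 17 depleted genes, the count was 29 without the filter, 27 with a null from control guides, 11 with voom (RPS15A at adjusted p = 0.644, RPA3 0.183, RPS21 0.104, RP4-705D16.3 0.247, RP11-315I20.1 0.173 and AC093702.1 0.865 lost their call), 8 by permutation of the mean and 1 above a mean of 100, where 473 genes were tested; over left-out clones and libraries it ran from 4 to 14, the lowest without D0 of clone 1 and without D12 of clone 6. With the clone as a block (the pairing) it was 16, with 13 shared: SNHG12 (adjusted p = 0.114), RP11-573G6.10 (0.072), AC093702.1 (0.67) and RP11-386G11.10 lost their call, and KB-1043D8.6 (0.0324), RPA1 (0.0123) and 1 other gene gained one. Guides called were 0 in the main model, 292 with the clone block, 382 with the block and no filter, and 0 to 81 over left-out libraries, 81 without D12 of clone 1. The number of enriched genes, 1 in the main model, was 0 without the filter, with controls centred, with the clone block, with a null from controls, with voom, with ranks by log2 fold change and with no filter plus block, 2 above a mean of 100, and 0 to 1 over left-out libraries; AC019117.1 was not among those called above a mean of 100 (adjusted p = 0.469) or without D12 of clone 1 (0.889).

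Genes differing between clones were 16 without the filter, 14 of them lower in clone 1, and 0 above a mean of 100; there the clone correlation was 0.117 and the control difference 0.012 (p = 0.316). Over left-out clones and libraries, RP4-705D16.3 ran from −2.23 to 0.43, RPS21 from −1.25 to 0.0556, RPA3 from −1.20 to 0.0408, RP11-315I20.1 from −0.40 to 0.0261, AC093702.1 from −0.16 to 0.0153 and KB-1043D8.6 from −0.56 to 0.0834, each lowest without D12 of clone 1 and turned without D12 of clone 6. RPS15A ran from −2.99 to −0.0265, RPS19 from −1.96 to −0.54 and RPA1 from −2.10 to −0.23. Leaving out 1 library breaks the pairing by clone, so that 1 clone is set against the D0 or D12 of both, and D0 levels differed between the clones. EPB41L4A-AS1 ran from −0.92 without D12 of clone 1 to −0.0263 without D12 of clone 6, and lost its call without D0 of clone 1 (0.312). PXN-AS1 ran from −0.55 to −0.11 and lost its call without D0 (0.312) or D12 (0.0617) of clone 1, LINC00493 from −0.40 to −0.0847, lost without clone 6 (0.349) or its D12 (0.59), and FGD5-AS1 from −0.21 to −0.0734, called only without clone 1. KB-1043D8.6 was 0.0082 without clone 6. PCBP1-AS1 ran from −0.0600 without D0 of clone 1 to 0.0097 without clone 6, and was 0.01004 above a mean of 100. It lost its call above a mean of 100 and without D0 of clone 6, D12 of clone 1 or D12 of clone 6. SNHG12 was −0.0213 with controls centred and ran from −0.0492 to 0.0068, below 0 without any 1 library. Shifts of clone-based names ran from 0.016 to 0.0764 and lost their call without D12 of clone 6, above a mean of 100 (0.0085) and among lncRNA targets (0.015). Without D12 of clone 6 core essential genes (−1.13 to −0.0324) and ribosomal proteins (−1.64 to −0.0456) also lost theirs. The snoRNA host genes gained a call without D0 of clone 1 (−0.0855, adjusted p = 0.0286). List shifts use gene medians, which the clone block leaves as they are. CRNDE stayed uncalled in each alternative for the whole gene (adjusted p 0.0723 to 0.991). The causes were not tested. Above a mean of 100, EPB41L4A-AS1 (adjusted p = 0.673), RP11-486O12.2 (0.186) and LINC00493 (0.902) were still tested and lost their call. RP11-486O12.2 also lost its call without clone 1, its D0 or its D12, and without D0 of clone 6. Its value ran from −0.33 without D12 of clone 1 to −0.26 without D0 of clone 1. Scaling to the same total is already that of the deposited values, and the count-based tests listed for recovered reads were not run; voom took their place. Most guides of the protein-coding targets lay under the filter, which reads the mean over D0 and D12 and so depends on the change itself.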

Other observations

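All tests of explanations in this part were chosen after the results were seen. Comparing the D0 libraries of the clones, over all guides with a read and 765 genes, 18 genes were lower in clone 6 and 0 higher by alpha-RRA (36 higher at an unadjusted p under 0.05), a comparison of 2 libraries. The 18 were the 12 protein-coding targets and 6 lncRNA targets: RP4-705D16.3 (median −1.44), KB-1043D8.6 (−0.60), EPB41L4A-AS1 (−0.47), RP11-315I20.1 (−0.28), RP11-290D2.6 (−0.25) and RP11-269F19.2 (0.03, where the rank test reads the lowest guides).

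The protein-coding guides were lower at D0 in clone 6 by a median of −2.05. Lower read depth of that library is argued against: after thinning clone 1 to the reads of clone 6 the median was −2.00, with −0.01 for control guides. Random loss of guides is argued against too, since none of 10000 random sets of 120 guides reached it (lowest −0.13; share 0.0001, the smallest they can give). Depletion under way before D0 and further along in clone 6 is a candidate explanation: the 13 lncRNA genes called from D0 to D12 were also lower at D0 in clone 6, with a median of −0.07 and 9 of 13 below 0, and random gene sets were as low in a share of 0.014. That comparison shares its D0 libraries with the calls; for the 9 lncRNA genes called in the test within clone 6 (5 of them also within clone 1), where a chance high at D0 of clone 6 would favour a call and work against the pattern, the median was −0.28, with 7 of 9 below 0 (share 0.0001). When guides were introduced relative to D0 is not given in the sources used here, and the clones may differ for other reasons that were not tested.

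Of PCBP1-AS1, SNHG12 and CRNDE, only PCBP1-AS1 had depletion in part of its guides with a spread between blocks beyond that of shuffled guides. In PCBP1-AS1, blocks 17, 18 and 19 of 19 had medians of −0.74, −0.19 and −0.26, and shuffling guides among blocks gave as large a spread in a share of 0.0001, the smallest possible (adjusted 0.0098 over 196 genes with more than 1 block, 4 of which passed, DLX6-AS1 and H1FX-AS1 among them), which argues against chance. The share was 0.0955 for SNHG12 (adjusted 0.535) and 0.0835 for CRNDE (adjusted 0.511), so chance could remain the explanation for the spread between blocks in both. Depletion of a single block against random guide sets is a separate question. SNHG12 block 4, at −0.29, passed that test (alpha-RRA adjusted p = 0.00227 among 1135 blocks, 0.00142 with the clone as a block). The third CRNDE block did not (0.165), except with the clone as a block (0.0431). In RP11-315I20.1, blocks 2 and 3 of 4 passed the same test, at −1.02 and −0.34 over 6 guides each (alpha-RRA adjusted p = 0.00662 and 0.0177). Its blocks 1 and 4 did not pass, at 0.04 and −0.27. Shuffled guides matched its spread between blocks in a share of 0.0018 (adjusted 0.0706). Whether blocks correspond to separate start sites cannot be read from the file, and no biological explanation was tested.

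A hypothesis prompted by PXN-AS1 was that targets within 5 kb of a listed essential gene are depleted through their neighbour. Only lncRNA targets with a known position entered, each with the median over its guides, which shows little of depletion in part of them. With PXN-AS1 included, 5 such targets had a mean 0.09 lower than 148 others (difference −0.09, permutation p = 0.0234). Without it 4 targets near an essential gene (NOP14-AS1, PRMT5-AS1, MMP24-AS1 and CASC11) differed by −0.02 (permutation p = 0.49). The p with all 5 thus rests on 1 target, and 4 others are too few to decide.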
